A study of Populus ussuriensis with 20 samples.

How the data were processed

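Gene expression was measured by RNA sequencing of total RNA from Populus ussuriensis (Ussuri poplar), a forest tree that is propagated from stem cuttings. Per the labels' protocols, cuttings were grown for 5 days on solid Woody Plant Medium until root primordia had formed. They were then moved to a modified liquid form of this medium with 10 or 200 µM KH2PO4, the phosphate source. The basal ends of the cuttings, with the primordia and the tissue around them, were collected 2, 4, 8, 12 and 24 h later. There were 2 libraries for each phosphate level and time, 20 in all. The labels number the libraries of each group but do not say whether they came from separate cultures or plants. The p-values then measure only the spread between these samples, which may be technical.

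The deposited values were FPKM, that is fragment counts scaled by gene length and by a library total of fragments, computed by the authors for 34699 genes in 20 libraries. The submitters' processing notes list HISAT2 2.1.0 and Bowtie2 2.2.3 without their roles. The reference genome, the annotation, the program that made the FPKM values and the treatment of reads shared by near-identical gene copies are not given in the sources used here. No sample of the table was left out, and the table held 0 further columns of values.

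Genes carried identifiers only. The files do not pair these with gene names or descriptions, and no genome or annotation was used here, so genes are neither described by function nor given coordinates. A set of gene lists (phosphate uptake and release, hormones, root meristem regulators, cell wall enzymes, cell type markers and others) had been fixed for limma's camera and fry tests. These lists were to be matched to gene descriptions, so they were void and no list test was run. The rule for named genes kept, for genes without a description, at most 2 identifiers that rose and 2 that fell in each comparison. They were the genes with the largest log2 differences among those past the threshold. In the mean comparison they also had to differ in the same direction at all 5 times, and in the comparisons of 24 h with 2 h both libraries of one group had to lie above both of the other. These rules, the tests and most alternatives were chosen before the data were examined.

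Depth was worked out from the steps between the low FPKM values, because each value is a whole number of fragments divided by the gene length and the library total. A search over lengths of 60 to 20000 bases gave 20 library totals from 14053677 to 15764764 fragments, a 1.12-fold range. The totals lay within 0.27 of a whole number before rounding. Whole fragments, to within 0.06 of a fragment, came out for all 24934 tested genes (100%), and each library's fragments summed to its total to within 7 to 38 fragments. The totals therefore count the fragments assigned to the genes of the table. On simulated fragments the recovery returned 99.99% of 27732 genes with at least 10 fragments in a library exactly, and all 20 totals. A tested gene had a median of 256 fragments per library. In a gene of 1 kb, 1 fragment corresponded to between 0.063 and 0.071 FPKM.

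Genes with an FPKM of at least 1 in at least 2 libraries were tested, which left 24934. Values were taken as log2(FPKM + 1) without further scaling between libraries. A fold change on this scale understates the change of genes with low FPKM. limma 3.58.1 in R 4.3.3 was fitted once to all 20 libraries with 1 mean for each phosphate level and time. Its variances were moderated with a mean trend, which gave a median of 14.1 total degrees of freedom per gene after moderation. Contrasts were 10 minus 200 µM at each time, the mean of these 5 differences, the variation of the difference over time (an F test), and 24 h minus 2 h at each level. Tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. The F test for variation with time of the mean over both levels, and the difference between the 2 changes from 2 h to 24 h, were added after the data had been seen.

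The limma fit was tested on simulated data with 200 of the 24934 genes changed. Noise was drawn independently for each gene from the fit's own variances. Deviations shared between genes were thus not simulated. The changed genes were drawn from those with a mean FPKM of at least 1, and the adjusted threshold is stricter where fewer than 200 genes change. For these reasons recovery in the real data may be lower. For the mean difference over 5 times the fit recovered 79% of changes of 1.5-fold, 95.5% of changes of 2-fold and 99% of changes of 4-fold. For a difference at 12 h alone it recovered 1% of changes of 1.5-fold, 65.5% of 2-fold and 92.5% of 4-fold. For variation with time, simulated as a change at 24 h alone on a flat profile, it recovered 45.5% of changes of 1.5-fold, 83.5% of 2-fold and 98% of 4-fold. False calls made up 3.4 to 4.8% of the calls for the mean difference, 0 to 6.4% at 12 h and 3.9 to 7.7% for time.

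Alternatives were a pseudocount of 0.1, no filter, a filter of FPKM 5, scaling to a common upper quartile, quantile normalization, robust variance moderation, the replicate number as a block, a minimum log2 difference of 1, fits on the 4 libraries of a comparison alone, an additive model, and leaving out each library in turn. When a library was left out, the lone library of its group was assumed to vary like the other groups. Chosen after seeing the data were limma's voom on the recovered fragments, a block for the libraries that share a time and a replicate number, and fits without the 4 libraries at 8 h. Random relabellings of the libraries were counted for the mean difference and for variation with time, 100 each with the real labels included. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.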

Results

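The data covered the first 24 h after poplar cuttings with newly formed root primordia were moved to low (10 µM) or higher (200 µM) phosphate, with 2 libraries for each of the 10 combinations of phosphate and time. The series title ties low phosphorus to adventitious root formation, the growth of roots from stem tissue. The comparisons therefore ask which transcripts in the rooting end of the stem differ with phosphate, when they differ, and how expression changes along the time course. Library totals lay between 14053677 and 15764764 fragments. The log2 differences between replicate libraries had SDs from 0.229 at 200 µM and 12 h to 0.430 at 10 µM and 8 h, and replicates correlated across genes with r from 0.9695 to 0.9912. No replicate pair was close enough to be 1 library deposited again, since the chi-square per degree of freedom between replicates was 4.42 or higher.

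Libraries were arranged by time rather than by phosphate. On the first principal component, which held 28% of the variance, all 4 libraries at 2 h lay between -39.4 and -14 and all 4 at 12 h between 13.5 and 32.5, whichever phosphate level they came from. Libraries at 4 h entered the 2 h range (-19.8, -21.5 and -20.5, the other at -4.4). Those at 24 h entered the 12 h range (24.4, 18.9 and 19.7, the other at 6.9). This component thus did not separate 2 h from 4 h or 12 h from 24 h. The second component held 14.9%, and all 4 libraries at 24 h lay at 11 to 33.6 on it, a range entered by 1 library each at 2 h and 8 h (both at 13.5 and 200 µM). It also split the libraries at 2 h, with replicate 1 at 8.5 (10 µM) and 13.5 (200 µM) and replicate 2 at -20.5 and -21.5. The libraries at 8 h were spread along the first component, and those at 10 µM lay at -15.3 (replicate 1) and 19.9 (replicate 2).

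**Figure D1:**
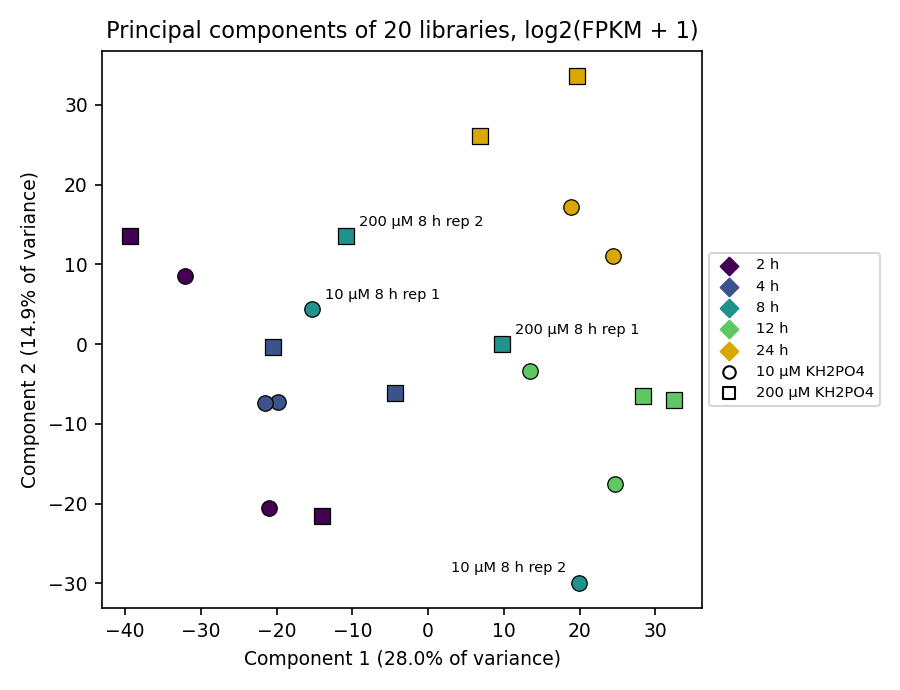
Each point is 1 of 20 libraries, placed by its scores on the first 2 principal components of log2(FPKM + 1). The horizontal axis holds 28% and the vertical axis 14.9% of the variance. Colours give the time after transfer, circles 10 µM and squares 200 µM KH2PO4. The 2 replicates at 10 µM and 8 h lie at -15.3 and 19.9 on the horizontal axis.

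Over the 5 times together, 11 genes differed between 10 and 200 µM KH2PO4, 7 higher and 4 lower at 10 µM. Potri.015G031400 was higher at low phosphate by 1.02 ± 0.14 (log2, SE), a 2.03-fold difference. It stood at 20.7 ± 2 FPKM (SD, n = 2) at 10 µM against 5.57 ± 0.23 FPKM (n = 2) at 200 µM after 24 h. Its log2 difference was largest at that time (1.72) and smallest at 12 h (0.42). Potri.005G107300 was higher by 0.88 ± 0.09 (1.84-fold), and after 2 h it measured 7.09 ± 1.2 FPKM at 10 µM against 2.36 ± 0.3 FPKM at 200 µM (SD, n = 2 each). Potri.010G236890 was lower at 10 µM, with a log2 difference of -0.51 ± 0.06 (0.702-fold), and Potri.011G047200 with -0.41 ± 0.06 (0.752-fold).

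The low-phosphate genes differed by moderate amounts, and most kept their sign along the time course. They were called on the mean of the same 5 differences, which favours genes with 1 sign throughout, so this agreement is not separate evidence. The 7 higher genes had mean log2 differences of 0.46 to 1.02, and the 4 lower genes of -0.51 to -0.31. Of these, 6 of the 7 higher genes and 4 of the 4 lower genes pointed the same way at all 5 times. Potri.005G107300 was higher at 10 µM by 1.26, 0.51, 0.69, 0.63 and 1.31 on the log2 scale at 2, 4, 8, 12 and 24 h. Both of its 10 µM libraries exceeded both 200 µM libraries at each of these 5 times. Potri.010G236890 was a weakly expressed gene, with 0.692 ± 0.025 FPKM at 10 µM and 1.68 ± 0.067 FPKM at 200 µM after 2 h (SD, n = 2 each). These values rested on 13 and 14 fragments per library at 10 µM and 33 and 34 at 200 µM. Its mean log2 difference was -0.78 with a pseudocount of 0.1 and -0.82 with voom on recovered fragments. Potri.011G047200 measured 10.4 ± 1.8 FPKM at 10 µM and 17.6 ± 0.51 FPKM at 200 µM after 4 h (SD, n = 2 each). The abundance of 8 of the 11 genes also varied with time.

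**Figure D2:**
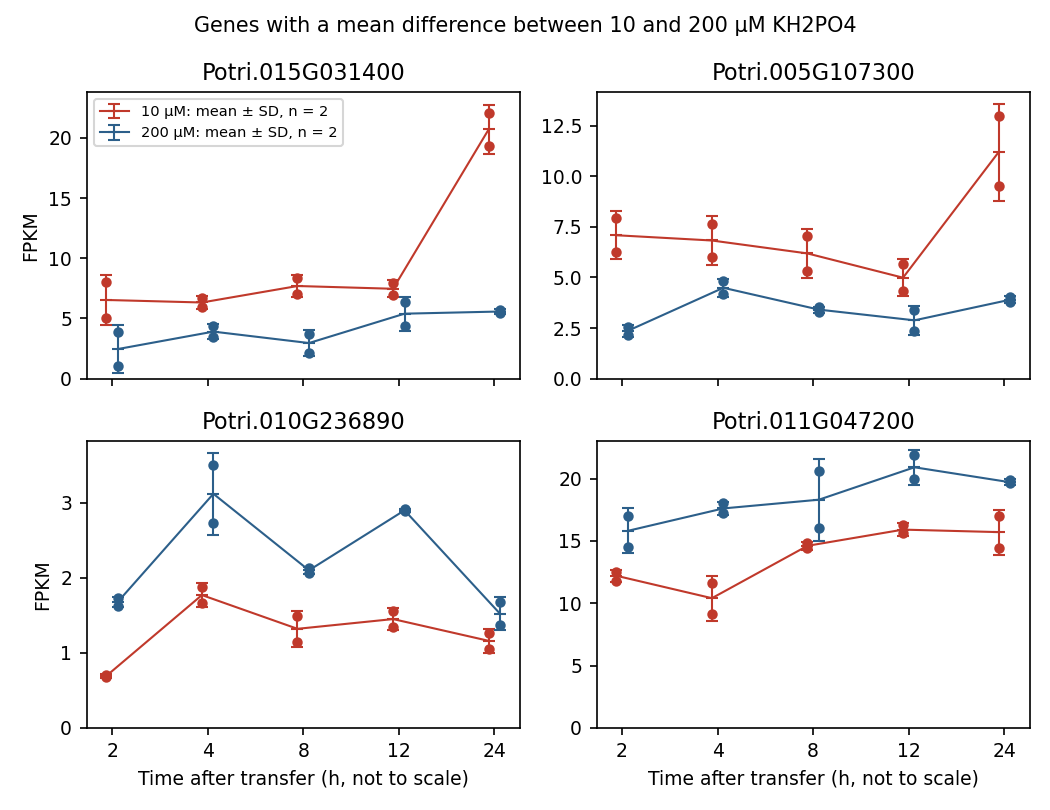
FPKM of the 4 named genes against time after transfer in h (time axis not to scale). Points are single libraries, horizontal ticks with bars are means ± SD of 2 libraries, red is 10 µM and blue 200 µM KH2PO4. Potri.015G031400 reached 20.7 FPKM at 10 µM and 5.57 FPKM at 200 µM after 24 h.

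In limma's test of the mean difference, the Benjamini-Hochberg adjusted p was 0.016 for Potri.015G031400, 0.00075 for Potri.005G107300, 0.0056 for Potri.010G236890 and 0.02 for Potri.011G047200. An unadjusted p under 0.05 in limma was reached by 1777 of 24934 genes (7.13%). Of the tested genes, 10.19% had the same sign at all 5 times, against an expected 6.25% for independent times. Genes are not independent replicates, and how far this share moves by chance was not tested. The median 95% confidence interval of a mean difference extended 0.16 (log2) on either side. The count fell to 6 without replicate 2 at 10 µM and 2 h, without replicate 1 or replicate 2 at 10 µM and 12 h, or without replicate 1 at 200 µM and 12 h. It was 7 without replicate 1 at 10 µM and 4 h, 10 µM and 24 h or 200 µM and 4 h, and without replicate 2 at 200 µM and 12 h, and rose to 25 without replicate 1 at 10 µM and 8 h. Potri.015G031400 and Potri.011G047200 both missed the threshold (limma, Benjamini-Hochberg adjusted p from 0.0542 to 0.0791) when any 1 of 6 libraries was left out. At 10 µM these were replicate 2 at 2 h, replicate 1 at 4 h, each replicate at 12 h and replicate 1 at 24 h, and at 200 µM replicate 1 at 12 h. Potri.011G047200 also missed it without replicate 1 at 200 µM and 4 h (0.073), replicate 2 at 200 µM and 12 h (0.0547) or replicate 2 at 200 µM and 24 h (0.0564). Without the 4 libraries at 8 h the count was again 11 genes, 9 of them shared, and Potri.015G031400 (log2 0.99, adjusted p 0.0872) did not pass. The rise without replicate 1 at 10 µM and 8 h rests on replicate 2 alone in that group. That library lay closest to the 12 h mean at 200 µM, so the rise cannot separate time from phosphate.

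At single times no gene passed the threshold between 10 and 200 µM KH2PO4. After 24 h the log2 differences were 1.72 for Potri.015G031400 and 1.31 for Potri.005G107300, and limma's smallest Benjamini-Hochberg adjusted p over all genes was 0.0928. The numbers of genes past it were 0 at 2, 4, 8, 12 and 24 h, while an unadjusted p under 0.05 was reached by 492, 895, 1485, 1132 and 1272 of 24934 genes (1.97, 3.59, 5.96, 4.54 and 5.10%). The smallest adjusted p was 0.165 at 2 h, 0.597 at 4 h, 0.692 at 8 h and 0.108 at 12 h. With limma's voom on recovered fragments, 4 genes passed at 24 h, all 4 of them higher at 10 µM and among the 11 genes above, and 0 at the other times.

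A gene at a single time had a median 95% confidence interval of 0.35 (log2) on either side. In data simulated at 12 h with 200 of 24934 genes changed, the adjusted threshold recovered 1% of 1.5-fold and 65.5% of 2-fold changes. Without replicate 1 at 10 µM and 8 h, genes did pass at 8 h, in a fit where the remaining library, replicate 2, stood alone in its group. That library lay closest to the 12 h mean at 200 µM (r = 0.43, against -0.22 for 8 h), so such calls cannot separate time from phosphate. Without all 4 libraries at 8 h, 11 genes passed at 12 h.

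The difference between phosphate levels did not vary detectably with time. In limma's F test 0 genes passed and 751 of 24934 (3.01%) had an unadjusted p under 0.05, with a smallest Benjamini-Hochberg adjusted p of 1. With voom on recovered fragments the count was also 0. For Potri.005G107300 the difference was largest at 24 h (1.31) and smallest at 4 h (0.51), and its adjusted p for variation with time was 1. Across genes, which are not independent replicates, the log2 differences at 2 of the times correlated with r between -0.03 and 0.17 over the 10 pairs of times (median 0.07). Some genes passed the F test without replicate 1 at 10 µM and 8 h. That group then held only replicate 2, which lay closest to the 12 h mean at 200 µM, so these calls cannot separate time from phosphate.

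Between 2 h and 24 h after transfer, 920 genes changed at 200 µM KH2PO4, with 674 higher and 246 lower at 24 h. Potri.013G128800 rose from 4.47 ± 0.18 to 82.2 ± 11 FPKM (SD, n = 2 each), a log2 change of 3.92 ± 0.48 (SE). Potri.014G149700 rose from 0.266 ± 0.19 to 13.9 ± 11 FPKM, a log2 change of 3.35 ± 0.38. Its libraries held 12 and 4 fragments of this gene at 2 h, and 199 and 677 at 24 h. The size of this rise was uncertain: the log2 change was 5.12 with a pseudocount of 0.1, 5.58 with voom on recovered fragments, 4.15 without replicate 1 at 24 h and 2.56 without replicate 2 at 24 h. Potri.009G034600 fell from 45.8 ± 9.7 to 4.74 ± 0.21 FPKM, a log2 change of -3.01 ± 0.21, and the short gene Potri.011G041124 (177 bases) from 75.8 ± 20 to 7.34 ± 3.2 FPKM, a log2 change of -3.23 ± 0.40. limma's Benjamini-Hochberg adjusted p values were 0.00091, 0.00061, 1.7e-05 and 0.00095 in this order. In a fit on these 4 libraries alone 8 genes passed, and Potri.014G149700 (adjusted p 0.11) and Potri.011G041124 (0.0543) did not. The count was 498 without replicate 1 at 2 h, 472 without replicate 2 at 2 h, 556 without replicate 1 at 24 h and 101 without replicate 2 at 24 h.

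At 10 µM KH2PO4, 603 genes changed over the same interval, 404 higher and 199 lower at 24 h. Potri.013G128800 rose here too, from 4.56 ± 2.2 to 97.5 ± 3.3 FPKM (SD, n = 2 each) with a log2 change of 4.21 ± 0.48 (SE). Potri.004G023200 rose from 1.81 ± 0.66 to 25.2 ± 3.7 FPKM (log2 3.23 ± 0.48). Potri.001G273600 fell from 116 ± 2.3 to 13.6 ± 0.97 FPKM (log2 -3 ± 0.27), and Potri.011G041124 from 67.4 ± 15 to 5.95 ± 3.6 FPKM (log2 -3.39 ± 0.40). limma's Benjamini-Hochberg adjusted p values were 0.001, 0.0044, 0.00016 and 0.0012 in this order. With quantile normalization between libraries the split was 327 higher and 254 lower. The count was 1092 without the 4 libraries at 8 h, which were no part of this contrast but set the shared variance, 267 without replicate 1 at 2 h, 122 without replicate 2 at 2 h, 85 without replicate 1 at 24 h and 56 without replicate 2 at 24 h. Potri.004G023200 missed the threshold without replicate 2 at 2 h (limma Benjamini-Hochberg adjusted p 0.0501) or replicate 2 at 24 h (0.0633).

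The changes from 2 h to 24 h were shared between the phosphate levels. Of the genes that passed, 328 did so at both levels: 239 rose at both, where 10.92 would be shared by independent lists of these sizes, 89 fell at both, where 1.963 would be, and 0 went in opposite directions. Both tests used the same variance estimate for each gene, so the lists are not independent and these reference numbers may be too low. Of the 920 genes called at 200 µM, 904 (98.3%) had the same sign at 10 µM, as did 592 of the 603 called at 10 µM (98.2%) at 200 µM, against 69.5% of all tested genes. Across genes, which are not independent replicates, the changes at the 2 levels correlated with r = 0.68, and they came from separate libraries. Libraries at 2 h that shared a replicate number deviated together across the levels (r across genes 0.5). Such shared deviations can enter both changes and their agreement. No single gene's change was shown to differ between the levels: limma's test of the difference of the changes gave 0 genes past the threshold and 887 of 24934 (3.56%) with an unadjusted p under 0.05, at a smallest Benjamini-Hochberg adjusted p of 1.

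**Figure D3:**
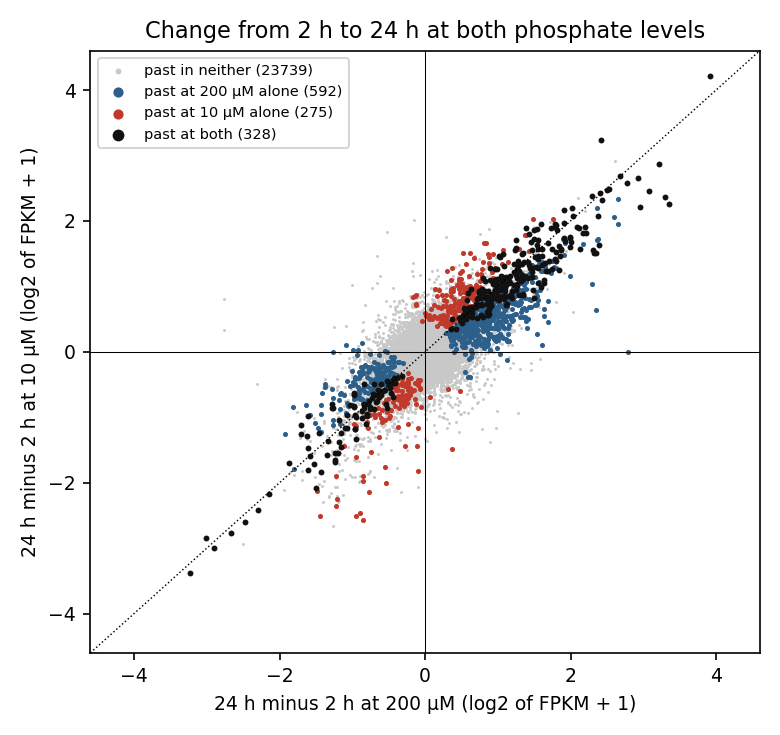
Each point is 1 of 24934 tested genes, with its log2 change of FPKM + 1 from 2 h to 24 h at 200 µM KH2PO4 on the horizontal axis and at 10 µM on the vertical axis. The dotted line marks equal change. Black points (328 genes) passed limma's threshold at both levels, blue points (592) at 200 µM alone and red points (275) at 10 µM alone. All 328 black points lie in the quadrants of equal sign.

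Over all 5 times and both phosphate levels, 3632 genes varied with time, the largest count of the comparisons made. The median range between the highest and lowest of the 5 time means was 0.66 (log2), and 775 genes had a range of at least 1. The profiles over the 5 times correlated between the levels with a median r of 0.85 and were positively correlated in 99.8% of these genes, which were chosen on the mean of both levels. Potri.009G034600 was lower at each later time. At 10 µM it went from 44.7 ± 2.5 FPKM at 2 h through 28.4 ± 5.8, 20.6 ± 1.9 and 14.2 ± 1.4 to 5.33 ± 0.1 FPKM at 24 h (SD, n = 2 each). Potri.013G128800 went from 4.56 ± 2.2 FPKM at 2 h through 1.72 ± 0.87, 9.96 ± 9.2 and 38.3 ± 0.68 to 97.5 ± 3.3 FPKM at 24 h. Its 2 libraries at 8 h measured 3.43 and 16.5 FPKM. The count of 3632 was 2072 without replicate 2 and 2237 without replicate 1 at 200 µM and 12 h, 2348 and 2409 without replicate 2 and replicate 1 at 10 µM and 24 h, 2384 without replicate 2 at 10 µM and 12 h, and 2412 without replicate 2 at 200 µM and 24 h. It was 5526 without the 4 libraries at 8 h.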

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

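The tests of an exchanged label and of a later position along the time course were chosen after the result had been seen. The relabelling of the mean difference and the test of counting noise were planned, whereas the variation with time was itself a comparison added after the data had been seen.

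Potri.017G063500, chosen after its values were seen, was 1 of the 7 genes that were higher at 10 µM KH2PO4 over the 5 times, and the only one of them that pointed the other way at a time: its log2 difference was -0.20 at 8 h and 0.92, 0.47, 0.49 and 0.96 at 2, 4, 12 and 24 h. At 8 h both libraries at 200 µM (10.7 and 10.3 FPKM) lay above those at 10 µM (9.63 and 8.42 FPKM). The variation of its difference with time had an unadjusted p of 0.00048 in limma and a Benjamini-Hochberg adjusted p of 1 over all genes, so it did not pass there. It passed with p adjusted over the list alone, the 7 higher genes, which were chosen on these samples (0.0033).

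The mean difference of 11 genes was compared with random exchanges of the phosphate labels within each time. Of 100 relabellings, the real one included, 1 gave as many genes as the real labels, and the highest of the others was 10. The real count was thus the highest of those drawn. With so narrow a margin, and 100 of 3888 possible relabellings drawn, chance was made less likely but cannot be excluded. The number of genes with an unadjusted p under 0.05 was less unusual: 20 of the 100 relabellings, the real one included, had at least the real 1777, and the highest had 4605. Why some relabellings gave so many was not tested. With the 4 libraries at 8 h left out the count was again 11 genes, of which 9 were shared.

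The variation with time (3632 genes) was tested by relabelling the times within each phosphate level. Of 100 relabellings, the real one included, 1 gave as many genes, and the highest of the others was 497. Without the 4 libraries at 8 h, in a fit that was not relabelled, 5526 genes varied with time. The real count was the highest of the 100 drawn, so chance was made less likely but cannot be excluded. The relabelling treats the 2 libraries of a group as independent, which the labels do not state. If they shared a culture, splitting them would favour the real labels. Time after transfer runs together with age, with time of day in a room with light and dark periods, and with the handling at transfer. No biological explanation was tested, since the design does not separate these.

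Replicate 2 at 10 µM and 8 h stood apart from its replicate, with an SD of 0.430 for the log2 differences between them. Its depth of 14053677 fragments was the lowest of the 20 libraries, but over genes with at least 1000 fragments the SD was 0.366, above the highest of the other groups (0.322), which argues against counting noise. A swap with a 10 µM library of another time, such as 12 h, would set that library's group apart along the same axis, but across genes replicate 2 minus replicate 1 correlated with the change from 8 h to 12 h at 200 µM with an absolute r of at most 0.14 in the other 10 µM groups (0.05 at 12 h), under the 0.24 reached at 200 µM, which argues against it. At 10 µM and 8 h that correlation was r = 0.59, and replicate 2 was closest to the 12 h mean at 200 µM (r = 0.43, against -0.22 for 8 h), while replicate 1 matched 2 h and 8 h about equally (0.31 and 0.29). The 200 µM libraries at 8 h did not match the 10 µM mean at 8 h either (0.01 and -0.02), but that mean includes the library in question. Replicate 1 at 200 µM was closest to the 10 µM mean at 24 h (r = 0.33) and replicate 2 to that at 4 h (0.11). Of 20 libraries, 16 were closest to their own time at the other level, and the rest were those at 8 h. The change from 8 h to 12 h at 200 µM itself rests on these 200 µM libraries. The r of 0.59 is consistent with tissue that was further along the time course, and a lone wrong time label or a different state of the cuttings at 8 h stay open.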

How the results depend on the processing

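Fits with voom, with a block within each time and without the libraries at 8 h were chosen after seeing the data. Under every scaling, pseudocount and filter the mean difference gave 10 to 14 genes, and of 235 values of named genes under alternatives 213 kept sign and call, 22 missed the threshold and 0 reversed. Without a filter 1 gene each passed at 4 h, at 12 h and for variation of the difference with time (cause not tested); with a minimum log2 difference of 1 the mean difference gave 1, 200 µM 382 and 10 µM 249, by construction. Fits on the 4 libraries of a comparison, with fewer degrees of freedom, gave 8 at 200 µM and 407 (257 shared) at 10 µM. voom gave 4 at 24 h, and the cause was not tested. The additive model gave 14 genes for the mean, 7 higher and 7 lower at 10 µM, of which 10 were shared. The number of lower genes thus depended on the model. Without the libraries at 8 h, whose replicates at 10 µM differed most, 5526 genes varied with time, 1092 changed at 10 µM, 11 genes passed at 12 h between phosphate levels and 11 for the mean. Leaving out 1 library gave 6 to 25 for the mean (lowest without LP 2 h replicate 2, highest without LP 8 h replicate 1, LP being 10 µM and P 200 µM), 0 to 31 for its variation (31 without LP 8 h replicate 1), 2072 to 5188 for time (without P 12 h replicate 2 and without LP 8 h replicate 2), 56 to 267 at 10 µM, 101 to 556 at 200 µM, 0 to 1 at 2 h (1 without LP replicate 2 or either P replicate), 0 to 1 at 4 h (1 without LP replicate 2 or P replicate 1), 0 to 352 at 8 h (352 without LP replicate 1, 1 without LP replicate 2 or P replicate 1), 0 to 0 at 12 h and 0 to 2 at 24 h (2 without P replicate 1, 1 without LP replicate 2). With the replicate block the counts were 11 for the mean, 836 at 200 µM, 544 at 10 µM, 3481 for time and 0 elsewhere; a block within each time gave 8 for the mean (7 higher, 1 lower), of which 6 were shared, and Potri.010G236890 (limma, Benjamini-Hochberg adjusted p 0.112) and Potri.011G047200 (0.138) missed the threshold. Libraries sharing a time and a number deviated together at 2 h (r across genes 0.50) but not at 4, 8, 12 and 24 h (0.07, -0.24, 0.07 and -0.01). The numbers thus do not pair the samples at those later times, but at 2 h the libraries grouped by number. This shared deviation can enter the comparisons that use 2 h. With quantile normalization the split at 200 µM was 476 higher and 263 lower. The counts without LP 8 h replicate 1 rest on replicate 2 alone in that group. It lay closest to the 12 h mean at 200 µM, so these counts cannot separate time from phosphate. The tests of gene lists, with their alternatives, were not run. Depth limits weak genes such as Potri.010G236890, which had 13 to 68 fragments per library.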

Other observations

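The F test over the list of genes higher at 10 µM was chosen after the result had been seen, as was the description of the time course. The test of consecutive identifiers was fixed before its result was seen.

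Among the 3632 genes that varied with time, the mean over both phosphate levels was highest at 24 h in 1240 (34.1%), at 2 h in 845, at 12 h in 784, at 4 h in 622 and at 8 h in 141 (3.9%). Over all tested genes the shares were 28.2% at 24 h, 19.1% at 2 h, 24% at 12 h, 16.9% at 4 h and 11.8% at 8 h. The 8 h means average libraries that stood apart (-15.3 and 19.9 on the first principal component at 10 µM), which bears on the counts at 8 h and on the steps next to it. Lowest values fell at 2 h in 1195 genes and at 12 h in 1000. The largest step between consecutive times lay between 12 and 24 h in 1040 genes, of which 736 rose and 304 fell. It lay between 4 and 8 h in 995, between 8 and 12 h in 993 and between 2 and 4 h in 604. The interval from 12 to 24 h was the longest and that from 2 to 4 h the shortest, so these counts do not compare rates of change. Potri.001G273600 went at 10 µM from 55.7 ± 15 to 13.6 ± 0.97 FPKM (SD, n = 2 each) between 12 and 24 h, and at 200 µM from 50.4 ± 1.5 to 14.8 ± 0.53 FPKM. Potri.004G023200, in contrast, stood at 23 ± 0.12 FPKM at 12 h and 25.2 ± 3.7 FPKM at 24 h at 10 µM, after 1.77 ± 0.086 FPKM at 4 h.

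In 6 of the 7 genes higher at 10 µM over the 5 times, the estimated difference was larger at both 2 and 24 h than at 4, 8 and 12 h. Potri.005G107300 averaged 1.28 (log2) at 2 and 24 h and 0.61 at the other times, and Potri.015G031400 averaged 1.48 and 0.72. These times were picked from the same values, so the contrast between them was not used as a test. limma's F test for variation of the difference over all 5 times, which picks no times, passed for 1 of the 7 genes (Potri.017G063500) with p adjusted over the list alone, a list itself chosen on these samples, and for 0 genes over all genes tested. Whether the differences vary along the time course therefore stays open.

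Genes with consecutive identifiers changed together between 2 h and 24 h more often than chance. At 200 µM, 61 pairs of called genes held consecutive identifiers among the tested genes of one numbering series and the same direction, 53 rising and 8 falling, where 10000 random draws of as many genes gave a mean of 20.6 and at most 39 (permutation p = 1e-04, the smallest these draws can give). At 10 µM there were 31 pairs, against a mean of 8.14 and at most 21 in random draws (permutation p = 1e-04). If identifiers run along the chromosomes, neighbouring genes that share regulation may account for this, and so could near-identical tandem copies that share fragments; without sequences these were not separated.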
